A study of Escherichia coli str. K-12 substr. MG1655 with 8 samples.

How the data were processed

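Escherichia coli K-12 MG1655, a laboratory strain, was grown at ambient temperature as planktonic cultures and as biofilms, with and without oxygen, per the labels' protocols. Total RNA was depleted of ribosomal RNA and made into Illumina libraries. The labels name 8 libraries in 4 groups of 2: aerobic planktonic, anaerobic planktonic, aerobic biofilm and anaerobic biofilm. They state neither how the replicates arose nor any pairing between groups.

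The values deposited by the authors are a score called an expression level, given per gene as a whole number in 1 column per group, per the file headers. The headers name a group and no replicate, and how the 2 libraries of a group enter its column is not given in the sources used here. The spread between them is not analysed here. The aligner, the counting method, the normalization and the genome build are not given in the sources used here. Depth is unknown, so no counting interval or detection limit is given. The sum of the levels in a column depends on that unstated normalization and is not a depth.

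The table listed 4321 genes, of which 4317 locus tags matched the reference gene table of assembly ASM584v2 and 4 did not. That table served only for gene names and for the order of genes along the chromosome. Because the authors' build is not named, no coordinates are given. The 111 ribosomal and transfer RNA genes were left out, as were 13 genes with a mean level under 1 over the 4 columns, which left 4197 genes.

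The plan written before the data were examined called for a test on separate libraries and, where only group values were found, for no test with values given as the authors'. The second case applied, so no p-value, standard error or significance call is given anywhere. A fold change is a difference of log2(level + 1), which understates the change of genes with low levels. It was taken relative to the median gene of the same comparison. A gene is called higher or lower where this value was at least 1 in size, which is 2-fold. This 2-fold rule in place of a test threshold, and the centring on the median gene as the main scale, were chosen after the values had been seen.

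Before the data were examined, 32 gene lists with 844 entries were fixed from general knowledge of E. coli, and 836 entries were found in the table. A set test needs replicates, so each list's median was instead placed among 10000 random lists of the same size drawn from 20 bins of mean level (seed 20). The percentile describes these columns and is not a p-value, since genes of an operon are not independent. This replacement was made after the kind of values was known. Of the 160 pairs of list and comparison, 58 lay in the outer 1 percent of their random lists (0.5 on each side). The lists named in the text come from these, together with 7 that were kept in view. Not every such pair is described, and the 7 are not given in every comparison, so a list left unnamed is not thereby unremarkable. The plot of list medians shows all 32. That choice of which lists to describe was made after the whole list table had been viewed.

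Genes are named by a rule fixed before the data were examined. It takes the 8 highest and 8 lowest folds per comparison (5 and 5 for the interaction) among genes with a mean level at or above the median of 59.5. It adds up to 4 members of each described list with the highest absolute fold, and 26 genes fixed by name. The part of the rule that asked for agreement between replicates could not be applied.

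To describe the lower end of each column, the 1069 genes lowest in planktonic culture (the lowest 25 percent) were taken. The 95th percentile of their levels in a column is called the top of the floor range of that column. This rule was added after the values had been seen. Alternatives were no filter on low levels, a mean level of at least 10, pseudocounts of 0.1 and 10, columns rescaled to the mean column and quantile normalization. Added after the values had been seen were the levels as deposited without centring, and calls kept only where the higher level lay above the floor range.

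On simulated columns made for the oxygen comparison in planktonic culture over 4197 genes, all 200 genes changed 4-fold were recovered in the right direction and 0 unchanged genes were called. Of 200 lists drawn with no effect, 2% lay in the outer 1 percent of their random lists. The noise in the simulation was chosen, not estimated from these data, and was small beside the 2-fold rule. Full recovery was therefore close to fixed in advance and gives no error rate for the calls below. The simulation does not include the raised floor of the biofilm columns. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.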

Results

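The series measured messenger RNA in E. coli MG1655 under 4 growth conditions that combine oxygen supply (aerobic or anaerobic) with culture type (planktonic or biofilm). Each condition had 2 libraries, and the authors' single group value per gene is what could be compared. There is no replicate error behind any value, so no difference below was tested against the spread between replicates.

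The 4 columns differed in shape before any gene was compared. The median level over 4197 genes was 42 in both planktonic columns, 66 in aerobic biofilm and 78 in anaerobic biofilm. The interquartile range on the log2 scale was 3.04 in aerobic planktonic, 2.99 in anaerobic planktonic, 1.04 in aerobic biofilm and 0.50 in anaerobic biofilm. Genes lowest in planktonic culture had median levels of 8 and 9 there, against 46 in aerobic biofilm and 74 in anaerobic biofilm. Their 95th percentile, the top of the floor range, was 15 in both planktonic columns, 75 in aerobic biofilm and 107 in anaerobic biofilm. Above it lay 3133 genes in aerobic planktonic, 3119 in anaerobic planktonic, 1714 in aerobic biofilm and 601 in anaerobic biofilm. The planktonic counts follow from the definition, because the lowest 25 percent of genes were chosen on planktonic level. Only the biofilm counts were free to vary. The rank correlation across genes was 0.974 between the planktonic columns, 0.773 between the aerobic columns, 0.598 between the biofilm columns and 0.285 between the anaerobic columns. Genes are not independent replicates, and these coefficients describe the columns only.

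**Figure D1:**
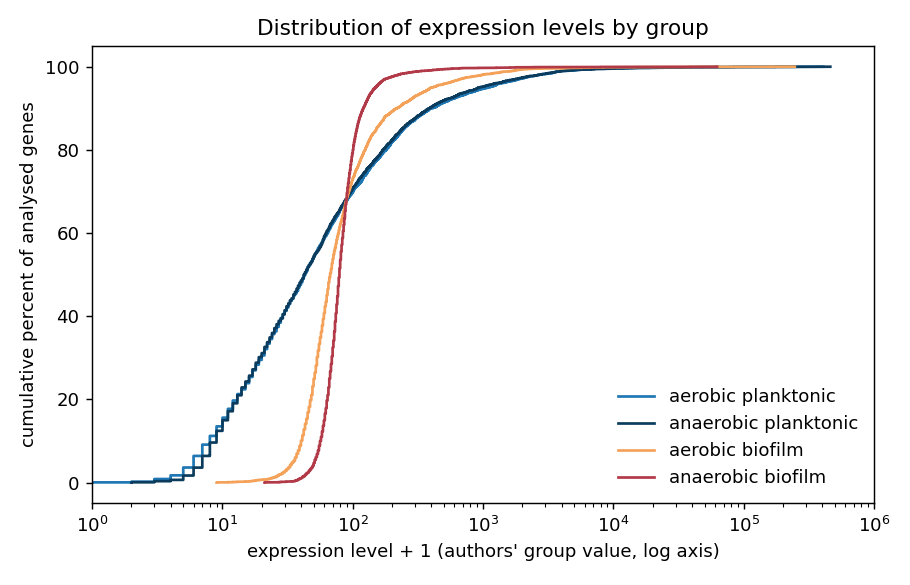
Cumulative percent of the 4197 analysed genes (vertical axis) at or below each expression level plus 1 (horizontal log axis), with 1 line per group value of the authors. The planktonic lines nearly coincide at a median of 42, while the biofilm lines are steeper, with medians of 66 and 78.

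**Figure D2:**
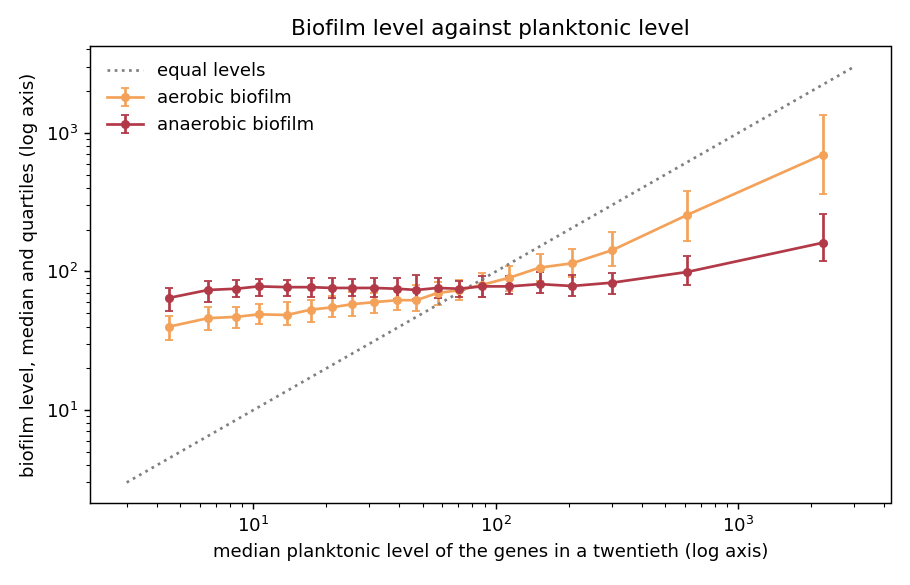
Median biofilm level with quartiles (vertical log axis) for 20 classes of genes ordered by planktonic level (horizontal log axis); the dotted line marks equal levels. In the lowest class the median planktonic level was 4.5 and the biofilm medians were 40 (aerobic) and 64.5 (anaerobic), and in the highest class 2225.5 against 696 and 161.

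The first comparison asks how planktonic cells differed with oxygen supply. The list of genes for hydrogenases and for formate hydrogenlyase, the complex that makes hydrogen from formate, was higher without oxygen. Of 30 measured genes of the hydrogenase and formate hydrogenlyase list, 14 were at least 2-fold higher and 0 lower, with a median log2 fold of 0.93 (percentile 100 of random lists). hycE (b2721), a hydrogenase 3 subunit, had a level of 138 without and 27 with oxygen, and hycC (b2723) 114 and 20. Nucleotide synthesis genes were higher as well, 14 of 30 with 1 lower, with a median of 0.79. Among them purK (b0522) and purE (b0523), which act in purine synthesis, stood at 127 against 25 and 135 against 32. soxS (b4062), a regulator of the superoxide response, had the highest fold of the named genes, at 462 against 76 (log2 fold 2.59).

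Genes of the general stress response and of acid resistance were lower in anaerobic planktonic culture. In the general stress list 16 of 30 were lower and 0 higher, with a median log2 fold of -1.07 (percentile 0). dps (b0812), a DNA-binding protein of stationary phase, had a level of 680 without and 5385 with oxygen. In the acid resistance list 9 of 17 were lower, with a median of -1.20 (percentile 0). gadE (b3512), its central activator, stood at 650 against 3650, and hdeB (b3509), a periplasmic acid chaperone, at 1048 against 5593. gadA and gadB encode near-identical enzymes whose reads could be shared, so their levels of 159 against 1070 and 228 against 1539 are uncertain. The curli fibre genes csgB (b1041) and csgA (b1042) were lowest of all, at 40 against 615 and 69 against 755, and the list median of 7 genes was -0.81.

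Smaller shifts of whole lists were also seen between the planktonic columns. Ribosomal protein genes had a median log2 fold of 0.61, with 1 of 54 at least 2-fold higher (rpsF, 938 against 453). Iron acquisition genes had a median of 0.57, with 2 of 39 higher. Of 9 type 1 fimbria genes 3 were higher, fimA (b4314) at 1125 against 474. In the cysteine and sulfur list 3 of 26 were lower, cysK (b2414) at 585 against 2959. Few respiratory genes passed 2-fold. None of the 37 anaerobic respiration genes was 2-fold higher (0 of 37, median 0.19), and narG had a level of 10 in both columns. The cytochrome bd oxidase gene cydA stood at 2455 against 2186, and the aerobic respiration list had a median of 0.28 with 0 of 23 past 2-fold, which was high among random lists (percentile 99.8). In the fermentation and glycolysis lists 0 of 19 and 0 of 17 were past it, and pflB, for pyruvate formate-lyase, stood at 10230 without and 12801 with oxygen. In all, 86 genes were higher and 128 lower without oxygen. Quantile normalization gave 29 and 48, and a pseudocount of 10 gave 48 higher.

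The next comparison asks the same of biofilms, where 29 genes were higher and 689 lower in the anaerobic column. All 54 ribosomal protein genes were lower, with a median log2 fold of -2.81 (percentile 0), for example rpmC (b3312) at 166 against 1905. fimA, the main subunit of type 1 fimbriae, had the lowest fold, at 288 without and 6492 with oxygen (log2 fold -4.75). The outer membrane porin gene ompF (b0929) stood at 142 against 1778 and the flagellin gene fliC (b1923) at 117 against 1227. Flagella and chemotaxis genes were lower in 16 of 52 (median -0.58, percentile 0) and cysteine and sulfur genes in 14 of 26 (median -1.17, percentile 0). cysK stood at 123 against 1904. Aerobic respiration genes were lower in 10 of 23, cyoA at 138 against 436, and nucleotide synthesis genes in 9 of 30, pyrB at 97 against 478. Above the floor range of the anaerobic biofilm column lay 50 of 54 ribosomal protein, 4 of 52 flagella, 3 of 26 cysteine, 5 of 23 aerobic respiration and 1 of 30 nucleotide synthesis genes. Prophage genes were the only list in the upper end of the outer 1 percent of random lists (median 0.52, percentile 100). Of the 45 prophage genes 3 were higher and 10 lower, and 2 lay above the floor range.

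Several other lists were low in the anaerobic biofilm column without standing apart from random lists of like level. Glycolysis genes were lower in 13 of 17 (percentile 57.1) and cold shock genes in 15 of 17 (percentile 25.7), with cspA at 221 against 2397. General stress genes were lower in 18 of 30, with a median of -1.25 (percentile 58.6) that turned to 0.46 under quantile normalization. dps, at 541 against 1855, turned from -2.03 to 0.48 in the same way. Anaerobic respiration genes were not low, with a median of 0.25 (percentile 65.2) and 0 of 37 past 2-fold. Of the glycolysis, cold shock, general stress and anaerobic respiration lists, 6 of 17, 6 of 17, 17 of 30 and 3 of 37 lay above the floor range. Without centring, 125 genes were higher and 515 lower, and quantile normalization gave 841 and 816. Higher were 3 with a pseudocount of 10 and 45 with rescaled columns. Of the 29 genes called higher, 1 lay above the floor range of the anaerobic biofilm column.

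Aerobic biofilm was set against aerobic planktonic culture to ask how growth on a surface differed with oxygen present. Motility genes stood out: 49 of 52 flagella and chemotaxis genes were higher in biofilm and 0 lower, with a median log2 fold of 2.39 (percentile 100). flgB (b1073), a basal-body rod protein, had a level of 238 against 3, and fliC of 1227 against 220. Above the floor range of the aerobic biofilm column lay 31 of the 52. The median level of the list went from 10 to 99, and that of a class of genes of like planktonic level from 10 to 49. Type 1 fimbria genes were higher in 7 of 9 (median 2.27), led by fimA at 6492 against 474, and 8 of the 9 lay above the floor range. The tryptophanase gene tnaA (b3708) and its leader tnaC (b3707) stood at 129 against 6 and 433 against 13.

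Further lists had higher members in aerobic biofilm. In the list of maltose, galactitol and other sugar uptake 27 of 45 were higher and 2 lower (median 1.53, percentile 100), malE (b4034), the maltose-binding protein, at 258 against 11 and malK (b4035) at 157 against 4. Cysteine and sulfur genes were higher in 19 of 26 and lower in 1 (median 1.95), sbp, a sulfate-binding protein, at 325 against 37. Nitrogen starvation genes were higher in 20 of 28 (3 lower), phosphate starvation genes in 15 of 22 (1 lower), and fatty acid and acetate genes in 16 of 21 (0 lower), acs at 111 against 6. Of these lists, 22 of 45, 17 of 26, 12 of 28, 5 of 22 and 9 of 21 members lay above the floor range, in the order given. The phosphate starvation list went from a median level of 10.5 to 53, near the 10 to 49 of a class of genes of like planktonic level. Exopolysaccharide genes were called higher in 23 of 30 and lower in 1, yet 1 of the 30 lay above the floor range. Their median level went from 6 to 46.5, near the 6 to 46 of a class of like planktonic level, although their percentile was 99.9.

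Heat shock and acid resistance genes were lower in aerobic biofilm, as were single genes of fermentation. In the fermentation list 9 of 19 were lower and 7 higher (percentile 25.9), with a median of -0.56 that turned to 0.092 without centring. pflB stood at 578 against 12801, grcA (b2579), which can replace the damaged part of pyruvate formate-lyase, at 1353 against 47514, and adhE, for alcohol dehydrogenase, at 159 against 1807. All 19 heat shock genes were lower (median -2.91, percentile 0.01), ibpA at 108 against 1076. Acid resistance genes were lower in 11 of 17 and higher in 4 (median -2.35, percentile 0.01), gadE at 91 against 3650. Of the fermentation, heat shock and acid resistance lists, 9 of 19, 17 of 19 and 9 of 17 lay above the floor range. arrS, a small RNA antisense to gadE, is uncertain because the sources used here do not say whether strand was used in counting. The cold shock gene cspI (b1552) had the lowest fold, at 303 against 13656. Ribosomal protein genes were lower in 38 of 54, with a median of -1.57 that was high for genes of their level (percentile 100) and turned to 0.51 under quantile normalization. General stress genes were lower in 21 of 30 and higher in 2, with a median of -1.54 (percentile 41.6) that turned to 0.051. In the anaerobic respiration list 15 of 37 were called higher and 13 lower, with 9 of the 37 above the floor range and a median of -0.41 (percentile 0) that turned to 0.24 without centring. In all, 1148 genes were higher and 1095 lower. Without centring the counts were 1768 and 554, and quantile normalization gave 494 and 454. A pseudocount of 10 gave 759 higher, and 192 of the 1148 lay above the floor range.

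Without oxygen, biofilm was again compared with planktonic culture. Abundant planktonic transcripts were lower: cspA (b3556), the main cold shock protein, stood at 221 against 48064, pflB at 142 against 10230, and gapA (b1779), for a glycolytic dehydrogenase, at 284 against 15251. All 17 glycolysis genes, all 17 cold shock genes and all 54 ribosomal protein genes were lower, with percentiles of 37.7, 1.39 and 0.755 among random lists of like level, and 6, 6 and 50 of them lay above the floor range. Formate hydrogenlyase and hydrogenase genes were lower in 12 of 30 and higher in 4 (median -0.50, percentile 0.01), a median that turned to 0.37 without centring, and 0 of the 30 lay above the floor range. The median level of this list went from 51.5 to 71, near the 48 to 73.5 of a class of genes of like planktonic level. The floor alone could thus give its median fold. fdhF stood at 62 against 1026. Iron acquisition genes were lower in 19 of 39 and higher in 4 (percentile 0.43), with 3 of the 39 above the floor range, exbD at 64 against 2796. The median level of the iron list went from 69 to 67, and that of a class of like planktonic level from 68 to 75. The median gene rose 1.83-fold, so such a class falls relative to it as well, and the floor could give part of the fold of the iron list. Anaerobic respiration genes were called higher in 16 of 37 and lower in 10, with 3 of the 37 above the floor range. Their median of 0.13 (percentile 0.16) turned to -0.17 under quantile normalization.

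General stress genes were lower in 18 of 30 and higher in 3, with a median of -1.58, which was high for genes of their level (percentile 100) and turned to 0.94 under quantile normalization. Flagella and chemotaxis genes were called higher in 43 of 52 (2 lower, median 1.93), sugar uptake genes in 33 of 45 (1 lower, median 1.91) and cysteine and sulfur genes in 15 of 26 (3 lower). Above the floor range lay 4 of 52, 12 of 45 and 3 of 26. The median level of the flagella list went from 9.5 to 75.5, and that of a class of genes of like planktonic level from 9 to 75. The floor alone could give the fold of that list. The cysteine and sulfur list went from 18 to 69.5, and a class of like planktonic level from 17 to 77. The floor alone could give the fold of the cysteine and sulfur list too. The sugar uptake list went from 14 to 89, against 13 to 77 for its class, so the floor could give much of its fold. fliC and fimA were lower, at 117 against 165 and 288 against 1125, and both turned higher under quantile normalization (0.80 and 1.39). tnaC stood at 253 against 5. In all, 1359 genes were higher and 1368 lower, without centring 2008 and 868, and 127 of the 1359 lay above the floor range.

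**Figure D3:**
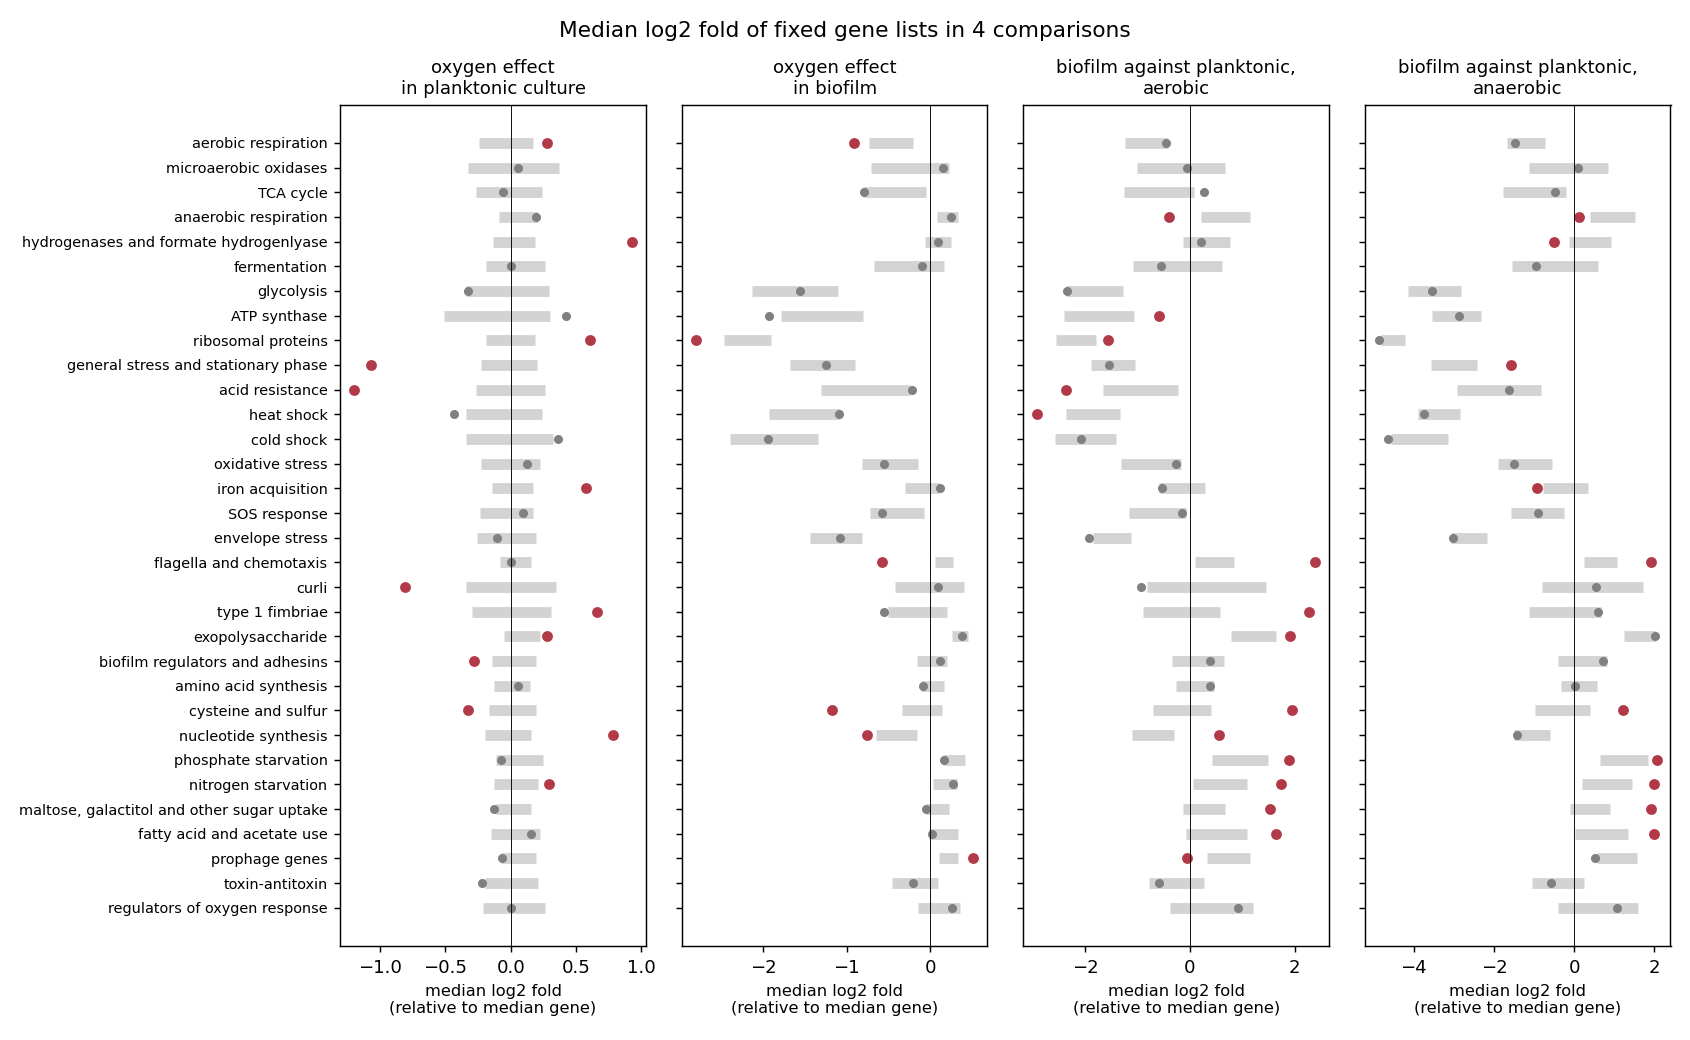
Median log2 fold of 32 fixed gene lists (horizontal axis, relative to the median gene, scale differing between panels) in 4 comparisons; grey bars span the central 95 percent of the medians of 10000 random lists and red points lie in their outer 1 percent (both sides together). Flagella and chemotaxis lie at 2.39 in the aerobic biofilm comparison, and ribosomal proteins at -2.81 in the oxygen comparison of biofilms. In the aerobic biofilm panel the ribosomal protein median of -1.57 turns to 0.51 under quantile normalization. Random lists were matched on mean level and not on planktonic level, so a list that only follows the biofilm floor can be red.

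**Figure D4:**
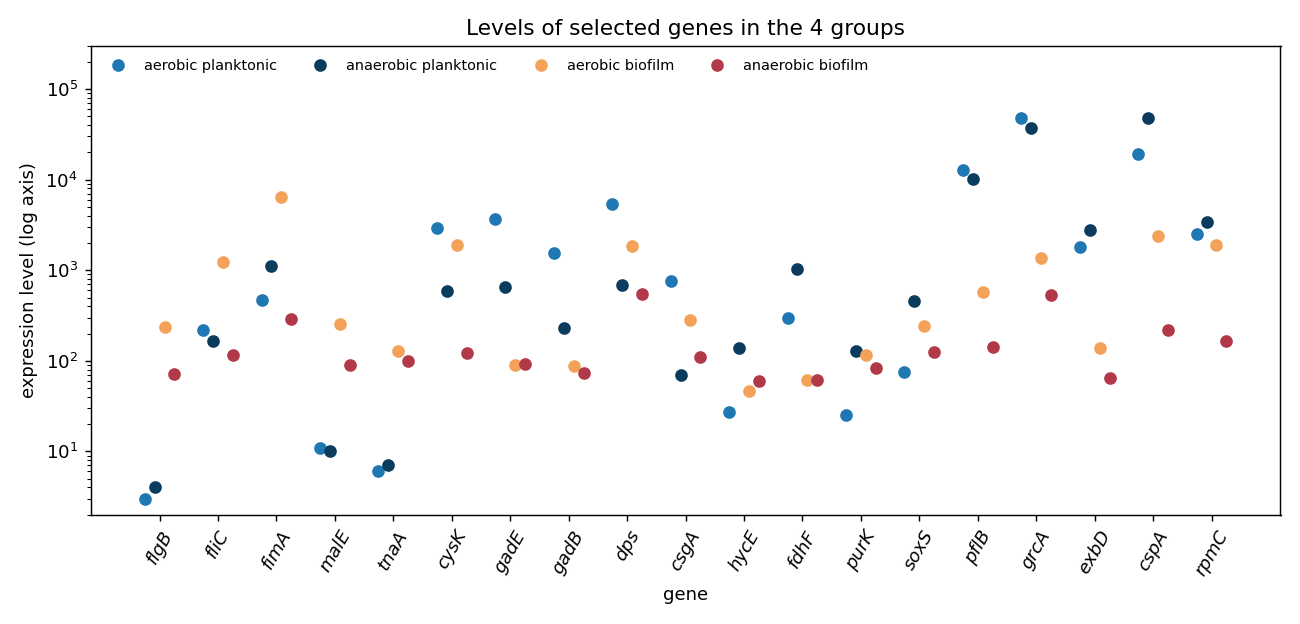
Expression level (vertical log axis) of 19 genes in the 4 groups, 1 point per group value of the authors. fimA spans 288 in anaerobic biofilm to 6492 in aerobic biofilm, and pflB 142 in anaerobic biofilm to 12801 in aerobic planktonic culture.

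The interaction asks whether the oxygen difference was the same in both culture types. It is the uncentred oxygen fold in biofilm minus that in planktonic culture, centred on its own median gene (0.21 before centring), and 194 genes were higher and 664 lower on it. fimA had the lowest value, at -5.94, followed by cspA at -4.98 and ompF at -4.40. All 54 ribosomal protein genes were lower (median -3.42), as were 19 of 30 nucleotide synthesis genes and 12 of 30 hydrogenase and formate hydrogenlyase genes, with 2 higher in each of these 2 lists. Acid resistance genes were higher in 7 of 17 (median 0.80, percentile 100), and curli genes in 3 of 7, csgB at 2.42. Of the 17 acid resistance genes, 9 lay above the floor range in aerobic and 4 in anaerobic biofilm, and of the 7 curli genes 2 and 2. Of the 30 hydrogenase and formate hydrogenlyase genes 1 and 0 did, and of the 30 nucleotide synthesis genes 22 and 1. Aerobic respiration genes were lower in 13 of 23 (median -1.12, percentile 0). General stress genes were higher in 3 and lower in 3 of 30 (median 0.065, percentile 100). Prophage genes were higher in 10 and lower in 8 of 45 (median 0.52, percentile 100). Above the floor range in aerobic and anaerobic biofilm lay 18 and 5, 23 and 17, and 12 and 2 members of these lists. Without centring 388 genes were higher and 524 lower, and quantile normalization gave 909 and 897. A pseudocount of 10 gave 74 higher.

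Across genes, the oxygen folds of the 2 culture types had a Pearson coefficient of 0.03 and a Spearman coefficient of 0.04, and 48.8% of genes had the same sign. Quantile normalization turned both coefficients negative, to -0.16 and -0.15, and a pseudocount of 10 gave a Pearson coefficient of -0.002. No gene was higher in both (0, against 0.594 for independent lists of the same lengths), 51 were lower in both (against 21.0), and 28 were higher in planktonic culture and lower in biofilm. The biofilm folds under the 2 oxygen conditions had a Pearson coefficient of 0.89 and a Spearman coefficient of 0.91, with 89.8% of the same sign. Under quantile normalization these were 0.588, 0.597 and 70.9%. Higher in both were 1043 genes (against 371.7) and lower in both 985 (against 356.9). Both pairs of comparisons share no column, yet the planktonic columns had a rank correlation of 0.974. Their log2 interquartile ranges of 3.04 and 2.99 exceeded the 1.04 and 0.50 of the biofilm columns. Both biofilm folds therefore carry nearly the same planktonic levels. High coefficients and overlaps would follow from that alone, to an extent not measured here. The floor of the biofilm columns enters both biofilm folds, so these overlaps hold the floor as well as any difference in transcripts.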

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

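The tests of explanations in this part were chosen after the results had been seen. Each gene below had an effect of at least 2-fold in one direction in one setting and in the other direction in the other setting, relative to the median gene. Without centring, 11 of the 13 oxygen effects and 6 of the 12 biofilm effects met that rule. These differences were not tested, since no replicate values were used. The difference given is the log2 fold in biofilm minus that in planktonic culture for the oxygen effect, and the log2 fold without oxygen minus that with oxygen for the biofilm effect. It is taken between folds that were each centred, whereas the interaction values of the report are centred on their own median gene. Apart from centring, the oxygen difference, the biofilm difference and the interaction are the same quantity for a gene. A gene flagged under both effects is therefore not separate evidence.

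The oxygen effect pointed in opposite directions for 13 named genes, each higher without oxygen in planktonic culture and lower without oxygen in biofilm. The difference was -5.99 for fimA, -2.98 for fimI and -2.88 for fimC, all type 1 fimbria genes. It was -5.03 for cspA and -4.44 for cspG, both cold shock genes. Nucleotide synthesis gave -3.85 for pyrB, -3.84 for pyrI, -3.25 for purC and -3.07 for purE. The remaining values were -3.81 for soxS, -3.78 for rpsF, -3.65 for glnA and -3.28 for grxA. Without centring, the folds in biofilm were -0.78 for purE and -0.97 for soxS, under 2-fold.

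The biofilm effect pointed in opposite directions for 12 named genes. In 11 of them the level was higher in biofilm with oxygen and lower in biofilm without it: the difference was -5.95 for fimA, -4.41 for ompF, -3.81 for pyrB, -3.80 for pyrI, -3.77 for soxS, -3.25 for grxA, -3.19 for fliC, -3.04 for purE, -3.01 for purK, -2.73 for pyrC and -2.29 for flgM. yhfZ went the other way, at 2.72. Without centring, the folds without oxygen were under 2-fold for flgM (-0.17), pyrC (-0.43), fliC (-0.49), purK (-0.61) and grxA (-0.80), as was that of yhfZ with oxygen (-0.45). For fimA and fliC the sign without oxygen turned under quantile normalization, to 1.39 and 0.80.

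Anaerobic biofilm, whose log2 interquartile range was 0.50, enters one side of each of these differences. A single scaling factor per column as the whole source of its shape is argued against, because a factor cannot narrow a range on the log scale, and the range in anaerobic planktonic culture was 5.93 times as wide. An even background, such as residual genomic DNA, may contribute. DNA of growing cells is richer near the replication origin. Of the 1069 genes lowest in planktonic culture, 1067 were placed in reference order. Their level fell with gene-order distance from the origin in anaerobic biofilm (Spearman coefficient -0.21) and in aerobic biofilm (-0.29). In the planktonic columns the coefficients were 0.001 and 0.007. These genes were chosen for low planktonic level, which narrows their range there, so the planktonic columns are not a free control. Turning the map gave coefficients as low in 2.53% of turns for aerobic biofilm and 9.56% for anaerobic biofilm. The lowest coefficients over turns were -0.293 and -0.217, so some other positions served slightly better than the origin in both columns. Whether the peak lies away from the origin or is broad was not tested. A lower content of messenger RNA per cell in the biofilms would raise the share of such a background, and that stays open.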

How the results depend on the processing

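No paired analysis was possible because each group has 1 deposited column, whose header names no replicate. For the same reason leaving out each library, the replicate block, fits of 2 groups, another test tool, a stricter p threshold and the set test with its variants were not run, and the planned rule on effect size became the main one. Depth is unknown, so no counting interval or detection limit is given. The levels without centring, the floor rule, and every alternative for the percentiles of the gene lists, as well as quantile normalization and no centring for the correlations, were chosen after the values had been seen. The lists whose members are named were narrowed after the values had been seen: before that step 45 values reversed, afterwards 25. A value is called reversed where it was at least 2-fold on the main scale and changed sign.

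Counts of genes stayed within 1.5 times with a mean level of at least 10 and with a pseudocount of 0.1. The setting with no filter kept the same 4197 genes, because the 13 genes left out were at 0 in every column. Its values were therefore fixed to equal the main ones and show no stability. They make up 160 of the list medians and 412 of the named-gene values counted in the next paragraph as having stayed. A mean level of at least 10 changed few calls, for example from 1148 to 1147 higher in aerobic biofilm. Under quantile normalization the planktonic oxygen counts were 29 higher and 48 lower, biofilm oxygen 841 higher, aerobic biofilm 494 higher and 454 lower, and the interaction 909 higher. With a pseudocount of 10 the higher counts were 48 for planktonic oxygen, 3 for biofilm oxygen, 759 for aerobic biofilm and 74 for the interaction. Rescaled columns gave 45 higher for biofilm oxygen. Without centring, higher counts were 125 for biofilm oxygen, 1768 for aerobic biofilm and 388 for the interaction, and lower counts 554 for aerobic and 868 for anaerobic biofilm. Kept above the floor range were 1 higher for biofilm oxygen, 192 for aerobic biofilm and 127 for anaerobic biofilm, since the rule drops genes by construction. Otherwise the cause was not tested.

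Quantile normalization moved the oxygen coefficients to -0.16 (Pearson) and -0.15 (Spearman) and the biofilm coefficients to 0.588 and 0.597, with 70.9% of the same sign. It forces the columns to 1 distribution, and each of these 25 reversals came from it. From 50 to 60 pairs of list and comparison lay in the outer 1 percent over the alternatives, against 58. Rescaled columns and no centring only add a constant to every gene of a comparison, and no filter keeps the same genes. Those settings were therefore fixed to give 58 and show no stability. A mean level of at least 10 and a pseudocount of 0.1 gave 60, a pseudocount of 10 gave 59 and quantile normalization 50. Of list medians, ribosomal proteins in aerobic biofilm turned to 0.51, and general stress to 0.46 for biofilm oxygen, 0.051 for aerobic and 0.94 for anaerobic biofilm. For biofilm oxygen, cydB turned to 0.47, ybgT to 0.90, cydA to 0.43, bolA to 0.44, dps to 0.48 and arcA to 0.18. In aerobic biofilm, atpC turned to 0.62, arcA to 0.38, fnr to 0.25, nuoA to 0.064 and narG to -0.53. In anaerobic biofilm, cyoA turned to 0.20, sra to 1.12, osmE to 0.56, arcA to 0.90, narG to -0.083, fliC to 0.80 and fimA to 1.39. On the interaction, cydB turned to 0.55, cydA to 0.26 and arcA to 0.52. Over 7 alternatives, 972 list medians stayed within 1.5 times and on their side of 2-fold, 144 moved and 4 reversed. Of values under 2-fold on the main scale, 26 of the 972 and 21 of the 144 changed sign, 13 of the 21 without centring and 8 under quantile normalization. For named genes 2327 values stayed, 536 moved and 21 reversed, and 7 and 12 of the first groups changed sign.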

Other observations

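The floor-subtracted values and the tests of explanations in this part were chosen after the data had been seen. To look past the floor of the biofilm columns, the median level of the genes lowest in planktonic culture was subtracted from each biofilm column, and 389 genes with a mean level of at least 300 were compared. The median gene then had 13.2% of its aerobic biofilm level in anaerobic biofilm, with 57 genes held at the lower limit of 10. General stress genes lay 1.41 log2 units above that median (15 genes, percentile 100 of random lists). Ribosomal protein genes lay 0.41 below it (54 genes, percentile 0.45). The central 95 percent of their random lists spanned -0.35 to -0.09, so genes of like level lay below the median as well. Those random lists could also hold the ribosomal protein genes themselves, which narrows their span. bssR, a regulator of biofilm formation, stood at 206% of its aerobic level, and fimA, fliC and ompF stood at 3.32%, 3.64% and 3.93%. These 4 genes were picked after their values were seen.

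Other settings were then run in every combination of 3 floors, 3 abundance limits and 3 lower limits, 27 in all. The general stress list lay in the upper end of the outer 1 percent of random lists in 27 of 27, although its distance from the median gene ranged from -0.077 to 1.73. Ribosomal proteins lay in its lower end in 16 of 27, with percentiles between 0.165 and 1.47 throughout and a distance from -1.60 to -0.23. Of 24 lists with enough members in some setting, the sugar uptake list was the other one to lie in the upper end in all of its settings (9 of 9). Flagella and chemotaxis lay in the lower end in 6 of 9, cysteine and sulfur in 3 of 9, nitrogen starvation in 2 of 9 and cold shock in 1 of 27.

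A run of 13 neighbouring genes from ynfG (b1589) to mdtJ (b1600), with ydgU, was listed at 0 in every column. Silent genes are argued against, because the lowest level of any other gene in anaerobic biofilm was 20. A deletion in the strain used may be the source, as the genes at 0 formed 1 unbroken run of 13 between ynfF and tqsA in reference order. Genes left uncounted in the authors' processing and then listed at 0 would look alike, and that stays open.

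The planktonic columns were close, with a rank correlation of 0.974, although one is labelled aerobic. That 1 library or pool stood behind both is argued against by 13 of 32 lists lying in the outer 1 percent between them. Whether a similar oxygen supply could account for the likeness stays open, because the lists point both ways. In the anaerobic respiration list 0 of 37 genes were 2-fold higher without oxygen, whereas in the hydrogenase and formate hydrogenlyase list 14 of 30 were higher and 0 lower (percentile 100). A swap of labels between columns was not tested, and oxygen itself was not measured in the data used here.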
